A study of Saccharomyces cerevisiae and Saccharomyces mikatae and Saccharomyces paradoxus with 13 samples.

How the data were processed

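RNA ratios from 13 S. cerevisiae cDNA microarrays with 2 colours were analysed, each array holding a treated or mated sample and its own reference. The 3 S. cerevisiae, 3 S. paradoxus and 4 S. mikatae alpha factor arrays compared a cells in YPD at 30 °C with 6 µM alpha factor for 60 min with untreated cells. The 3 mating arrays compared mixed BY4741 and BY4742 cells on a filter for 90 min with the same cells kept unmixed. Per the labels, the arrays of a species are biological replicates.

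The table holds the authors' deposited log2 ratio for each of 6132 ORFs, with 1 value per ORF and array. The log base, the centring, the direction, the scanner, the background correction, the normalization within arrays and the rule for missing values are not given in the sources used here. The values were read as log2 of channel 1 (treated or mated) over channel 2 (reference). Channel labels and the labelling protocol name the dyes of the treated sample differently, so the direction is likely rather than certain. Array medians lay between −0.00931 and 0.00805, and each array was centred on its median. Names came from the S. cerevisiae reference gene table, which matched 5665 ORFs, 43 of them after a dash was added, and 467 kept their own name. No sequences of S. paradoxus or S. mikatae were used, so mismatch between probe and RNA was not measured.

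Arrays were fitted together in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean per group. This left 9 residual degrees of freedom for genes measured on all 13 arrays and fewer for the others. Genes needed at least 2 measured arrays in each group compared. Group means were tested against 0, and differences between groups by contrasts, with moderated t tests, and any difference among the species by a moderated F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A test against 0 covers variation of the reference only where replicate arrays carried separate reference samples, which was not checked. Replicate numbers were checked for pairing between groups: 18 pairs of arrays with the same number correlated at −0.261 to 0.334 and others at −0.336 to 0.378, so no pairing was used.

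Gene lists were written from general knowledge: mating pathway components, cell fusion and mating projection, nuclear fusion, a-specific, alpha-specific and haploid-specific genes, meiosis and sporulation, G1/S, histones, G2/M and M/G1. Further lists covered ribosomal proteins, ribosome biogenesis, general stress, cell wall integrity, calcineurin targets, filamentous growth, respiration and the TCA cycle, glucose-repressed carbon use and glycolysis. The others were amino acid biosynthesis, sulfur and methionine, phosphate starvation, the iron regulon, ergosterol synthesis and reference genes, 26 lists in all. The cell wall list entry MLP1 matched the nuclear pore gene of that name. The a-specific list holds RAM1 and STE14, which process a-factor but are expressed in all cell types. Lists with at least 5 tested members were tested by cameraPR with an inter-gene correlation of 0.01 and adjusted over 203 list-by-comparison tests. The test was repeated with the correlation estimated per list, and with fry.

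Groups, comparisons, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names the 10 highest and 10 lowest called genes of a response that were measured on every array with the same sign. For a difference it names the 8 highest and 8 lowest called genes measured on every array of both groups, with no overlap between the arrays of the 2 groups, which chance gives in 10% of genes for 3 arrays against 3. It adds up to 4 members of each list described, and FUS1, FIG1, AGA1, PRM1, KAR4, STE2, BAR1, FAR1, FUS3, SST2, MFA1, CLN2, CLB2, HTB2, ACT1, STE3 and MF(ALPHA)1. Genes deleted in BY4741 or BY4742 (HIS3, LEU2, URA3, MET17 and LYS2) are named only with that remark. Members named to resolve a count of 5 or fewer, other genes outside the rule, and the probes of chromosome VIII were chosen after their values were seen.

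The alternatives were values with no centring, arrays scaled to a common spread, quantile normalization, only genes measured on all 13 arrays, only the arrays compared, array weights, robust eBayes, a log2 change of at least 1, a replicate block, and leaving out each array in turn. The procedure was tested on simulated data with known changes. Of 100 genes changed by 0.5 log2, 88 to 94 were recovered in responses and 57 to 69 in differences between groups. Of 50 genes changed by 1, 48 to 50 were recovered, and 3.39% to 8.95% of calls were false. The simulated noise was independent between genes and had the same spread on every array. Fewer genes were changed than were called in the real data, and in a single group only. Rates may differ for real arrays with correlated genes, unequal quality or many changed genes.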

Results

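The series asked how the mating response compares between 3 budding yeasts, Saccharomyces cerevisiae, S. paradoxus and S. mikatae. RNA was compared on 13 S. cerevisiae cDNA arrays, each of which carried a treated sample against its own reference sample. Haploid a cells of each species were sampled 60 min after 6 µM alpha factor, the peptide pheromone of alpha cells, and compared with cells taken before it was added. There were 3 such arrays for S. cerevisiae (BY4741), 3 for S. paradoxus (from CBS432) and 4 for S. mikatae. A further 3 arrays compared S. cerevisiae BY4741 and BY4742 cells that had been mixed on a filter for 90 min with the same cells kept apart. Of 6132 probes, 5678 to 5964 gave a value on the S. cerevisiae alpha factor arrays, 4367 to 4777 on those of S. paradoxus and 4253 to 4304 on those of S. mikatae. The mating arrays gave 3616 to 3740. Signal intensities were not used here, and the number of arrays limits the precision.

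All values below are log2 ratios of treated over reference cells. The labels conflict on which dye the treated sample carried, so this direction is likely rather than certain. It rests on the channel order and on the cell fusion list, chosen beforehand as the check, which went up. With the sign turned, every rise becomes a fall.

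In S. cerevisiae a cells exposed to alpha factor, genes for cell adhesion, membrane fusion and nuclear fusion were among those that rose most. Histone genes were among those that fell most. FIG1 (YBR040W), a membrane protein of the mating calcium response, rose by 4.97 ± 0.136 (SD, n = 3; 31.3-fold; adjusted p = 1.54e-12). PRM1 (YNL279W), which acts in plasma membrane fusion, rose by 4.67 ± 0.291 (25.4-fold) and PRM3, which acts in nuclear fusion, by 3.86 ± 0.222. The a-agglutinin genes AGA1 and AGA2 rose by 3.67 ± 0.375 and 3.16 ± 0.188, and the adhesin gene FIG2 by 3.37 ± 0.389. KAR4, a transcription factor of nuclear fusion genes, rose by 3.59 ± 0.3, ASG7 by 3.16 ± 0.166, and the unnamed ORFs YDR124W and YNL337W by 3.52 ± 0.528 and 3.31 ± 0.188. Among the 10 lowest, 6 were histone genes, with HTA2 at −2.81 ± 0.122, HHF2 at −2.69 ± 0.353 and HTB2 at −2.57 ± 0.0985 (adjusted p = 1.02e-07). The others were OLE1, the fatty acid desaturase, at −2.42 ± 0.343, SVS1 at −2.12 ± 0.256, the drug transporter FLR1 at −2.02 ± 0.141 and the purine synthesis gene ADE17 at −1.75 ± 1.06. FUS1 rose by 1.499 ± 0.21, the pheromone receptor gene STE2 by 1.10 ± 0.234 and the G1 arrest factor FAR1 by 1.86 ± 0.178. The G1 cyclin CLN2 was at 0.04 ± 0.0673, the mitotic cyclin CLB2 fell by 0.44 ± 0.13, and actin (ACT1) was at 0.08 ± 0.0433 (adjusted p = 0.451).

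The gene lists fixed beforehand showed the same division in S. cerevisiae. In the cell fusion and mating projection list 21 of 26 members rose and 1, PRM7, fell (camera adjusted p = 1.42e-76). This list also served as the check of the direction of the ratios, so the sign of its change is no separate result. Of 10 a-specific genes 8 rose (adjusted p = 1.26e-18), among them BAR1, the alpha factor protease, by 2.29 ± 0.537 and the a-factor gene MFA1 by 1.53 ± 0.0737. Of 26 mating pathway components 14 rose and none fell (adjusted p = 3.58e-12), with AFR1 up by 2.39 ± 0.159, the kinase FUS3 by 2.06 ± 0.19 and the negative regulator SST2 by 1.64 ± 0.0723. In the nuclear fusion list 6 of 14 rose, among them KAR5 by 2.77 ± 0.0804 and CIK1 by 1.99 ± 0.203, while JEM1 and CIN2 fell (adjusted p = 1.41e-12). The haploid-specific list had 8 of 19 higher and 2 lower, HO and RDH54 (adjusted p = 1.67e-06). The M/G1 list had 14 of 27 higher and 3 lower (adjusted p = 6e-06), with the glucanase SCW11 up by 1.97 ± 0.106 and the transcription factor TEC1 by 1.68 ± 0.167. Of 41 respiration and TCA cycle genes 20 rose and 1, COX12, fell (adjusted p = 0.00127), with 22 and 2 when adjusted over the list alone. Of 21 meiosis and sporulation genes 8 rose, led by IME4 at 1.66 ± 0.173 and SPO11 at 0.70 ± 0.0118. That list was past the threshold with the preset correlation (adjusted p = 0.0404) and not otherwise (adjusted p = 0.356 with an estimated correlation).

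Of 9 histone genes 7 fell in S. cerevisiae (adjusted p = 3.63e-34). The G1/S list had 22 of 37 lower, 25 when adjusted over the list alone, and 2 higher (adjusted p = 2.6e-08), with RNR1, the ribonucleotide reductase, at −1.52 ± 0.0818 and the cyclin PCL2 up by 2.88 ± 0.209. Of 64 ribosome biogenesis genes 46 fell, 52 when adjusted over the list alone, and 1, UTP7, rose by 1.02 ± 0.178 (adjusted p = 3.92e-11). That call was lost when gene correlation was estimated (adjusted p = 0.144 with an estimated correlation). DBP2 stood at −0.99 ± 0.167 and ERB1 at −0.98 ± 0.15. The other S. cerevisiae list calls given here held with an estimated correlation. Of 25 iron regulon genes 13 fell, 14 when adjusted over the list alone (adjusted p = 0.00101), with the transporter FET4 at −1.09 ± 0.296 and the reductase FRE1 at −0.89 ± 0.0747. These lists did not pass the set test: alpha-specific (2 higher and 1 lower of 6), G2/M (2 and 10 of 24), ribosomal proteins (1 and 4 of 130), general stress (11 and 3 of 41) and cell wall integrity (6 and 5 of 24). Nor did calcineurin targets (3 and 2 of 11), filamentous growth (5 and 5 of 13), glucose-repressed carbon use (2 and 3 of 25), glycolysis (1 and 1 of 19) and amino acid biosynthesis (4 and 9 of 43). The same held for sulfur and methionine (8 and 2 of 25), phosphate starvation (2 and 7 of 18), ergosterol synthesis (4 and 6 of 25) and the reference genes (2 and 1 of 11). Adjusted over the list alone, counts of these lists shifted by at most 3 genes. For the calcineurin list the median was −0.14 and the mean 0.04. PRM5 in the cell wall list rose by 1.75 ± 0.125 and the glucan synthase FKS1 fell by 1.24 ± 0.0154.

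In all, limma called 1946 of 5789 genes in S. cerevisiae after Benjamini-Hochberg adjustment, 946 higher and 1000 lower, of which 140 changed at least 2-fold. Without replicate 3 the count was 1124. On these arrays 31 to 39 probes per array shared identical values, for a reason that was not tested. Of these, 13 to 17 per array were ribosomal protein genes and 3 to 5 glycolysis genes. Paralogous genes such as histone pairs can cross-hybridise.

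**Figure D1:**
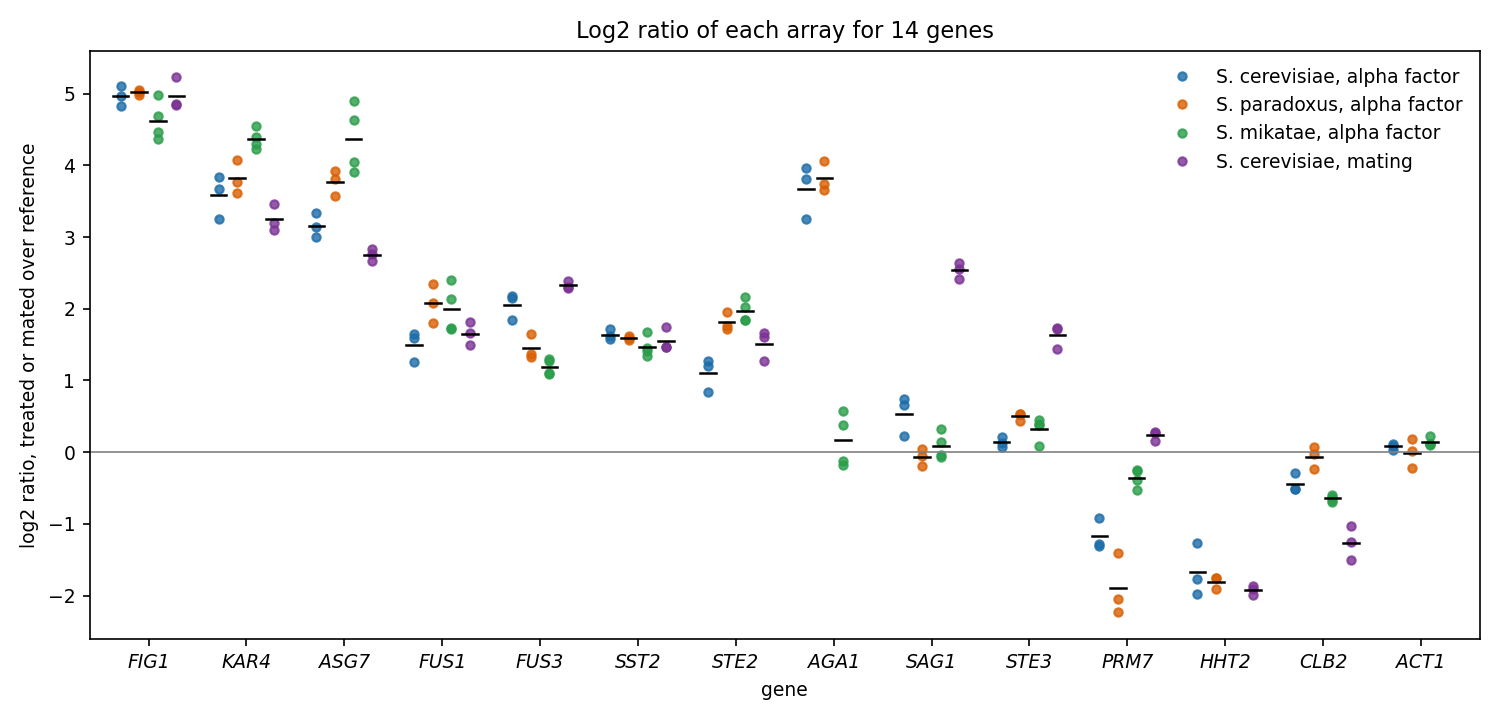
Log2 ratio of treated or mated over reference cells (vertical axis) for 14 genes (horizontal axis). Each dot is 1 array, colours mark the 4 groups and lines the group means; FIG1 means lie between 4.62 and 5.02, and AGA1 is at 0.17 in S. mikatae.

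In S. paradoxus a cells, several of the same mating genes rose. FIG1 rose by 5.02 ± 0.0378 (n = 3; 32.4-fold; adjusted p = 1.09e-12), KAR4 by 3.82 ± 0.233, AGA1 by 3.82 ± 0.218, ASG7 by 3.77 ± 0.178, YDR124W by 3.90 ± 0.313 and PRM1 by 3.58 ± 0.419. Also among the 10 highest were 4 probes outside the known mating genes: MAK32 at 4.30 ± 0.267, YCL076W at 4.13 ± 0.407, YCL075W at 3.91 ± 0.496 and YAL069W at 3.39 ± 0.356. The lowest included the copper transporter CTR1 at −2.07 ± 0.265, the phosphate transporter PHO84 at −2.07 ± 0.1, the aquaporin AQY1 at −1.96 ± 0.168, the asparaginase ASP1 at −1.87 ± 0.125 and the glutamine synthetase GLN1 at −1.82 ± 0.679. NIP7, a ribosome biogenesis factor, fell by 1.93 ± 0.261, PRM7 by 1.90 ± 0.431, YLL053C by 1.83 ± 0.0256, and the histone H3 genes HHT1 and HHT2 by 1.85 ± 0.0786 and 1.81 ± 0.0893.

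Of 22 cell fusion genes measured in S. paradoxus 16 rose and 1, PRM7, fell (adjusted p = 8.79e-38), and of 10 a-specific genes 9 rose (adjusted p = 2.35e-21), with BAR1 up by 3.15 ± 0.187. Mating pathway components had 14 of 26 higher (adjusted p = 8.17e-06) and 5 lower, STE4, DIG1, BEM1, PTP3 and MPT5. Nuclear fusion genes had 6 of 12 higher and JEM1 lower (adjusted p = 8.33e-11), and haploid-specific genes 7 of 17 higher and 3 lower, STE4, HO and RDH54 (adjusted p = 0.0166). Of 58 ribosome biogenesis genes 52 fell and UTP7 rose (adjusted p = 2.56e-18), with CIC1 at −1.47 ± 0.144 and DBP2 at −1.46 ± 0.462. Of 5 histone genes measured 4 fell (adjusted p = 0.000112). Glucose-repressed carbon genes had 10 of 23 lower (adjusted p = 0.012), among them PCK1, the gluconeogenic kinase, at −1.59 ± 0.48 and the hexose transporter HXT5 at −1.30 ± 0.174. Phosphate starvation genes had 10 of 14 lower and PHO86 higher (adjusted p = 0.00294), with 11 and 2 when adjusted over the list alone. The G1/S list had 15 of 35 lower and 2 higher, PCL2 and ELO1 (adjusted p = 0.0454, and adjusted p = 0.356 with an estimated correlation). M/G1 (6 higher and 7 lower of 24; adjusted p = 0.939), respiration (16 and 6 of 39; adjusted p = 0.129), the iron regulon (5 and 6 of 22; adjusted p = 0.798) and meiosis (4 and 0 of 20; adjusted p = 0.552) had no call as lists. Of 22 ergosterol genes 12 rose and 4 fell, with no call for the list (adjusted p = 0.0962), and ribosomal proteins had 2 higher and 9 lower of 71. The other S. paradoxus list calls held with an estimated correlation. Adjusted over the list alone, the counts with no other value given here were unchanged, apart from ergosterol synthesis (13 and 5), meiosis (2 and 0) and ribosomal proteins (1 and 4).

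limma called 2303 of 4748 genes in S. paradoxus, 1134 higher and 1169 lower, of which 194 changed at least 2-fold. The probes are S. cerevisiae sequences, 20.8% of them gave no value on any S. paradoxus array, and the effect of sequence divergence on the others was not measured.

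In S. mikatae a cells, FIG1 rose by 4.62 ± 0.271 (n = 4; 24.6-fold; adjusted p = 4.38e-13), KAR4 by 4.37 ± 0.137, ASG7 by 4.37 ± 0.469, YDR124W by 3.73 ± 0.454 and PRM1 by 3.502 ± 0.196. The cyclin PCL2 rose by 3.35 ± 0.617, AFR1, which shapes the projection, by 3.13 ± 0.251 and PRM10 by 2.97 ± 0.189. DCD1, the dCMP deaminase, rose by 2.91 ± 0.579 and YHR125W by 2.75 ± 0.264. AGA1 was at 0.17 ± 0.375 (adjusted p = 0.352). The lowest were the purine and serine metabolism genes ADE17 at −2.14 ± 1.09 and SHM2 at −2.09 ± 0.823, ASP1 at −2.13 ± 0.373, FLR1 at −2.01 ± 0.0823, YBL113C at −1.98 ± 0.0412 and ERG3, a sterol desaturase, at −1.96 ± 0.28. AQY1 fell by 1.93 ± 0.342, NIP7 by 1.82 ± 0.147, the mannosyltransferase MNN2 by 1.80 ± 0.28 and the glucose transporter HXT1 by 1.79 ± 0.157.

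Of 17 cell fusion genes measured in S. mikatae 12 rose and PRM7 fell (adjusted p = 5.27e-28). Of 6 genes on the a-specific list 5 rose (STE2, STE6, BAR1, ASG7 and RAM1; adjusted p = 6.96e-18), though RAM1 and STE14 on it act in all cell types, and of 23 mating pathway components 12 rose and 4 fell (adjusted p = 1.2e-07). Nuclear fusion genes had 3 of 8 higher (KAR3, KAR4 and CIN4) and 2 lower, BIK1 and JEM1 (adjusted p = 0.0102). Haploid-specific genes had 7 of 13 higher and 3 lower (adjusted p = 0.0117). Of 62 ribosome biogenesis genes 53 fell, 55 when adjusted over the list alone, and UTP7 rose (adjusted p = 1.09e-16), with ERB1 at −1.60 ± 0.182. Of 20 sulfur and methionine genes 13 fell and MET28 rose (adjusted p = 0.00739), among them the methionine synthase MET6 at −1.30 ± 0.202 and MET14 at −0.74 ± 0.521. In the filamentous growth list 3 of 5 rose (KSS1 by 1.63 ± 0.161, n = 3, TEC1 by 1.33 ± 0.106, n = 4, and PGU1 by 0.73 ± 0.149, n = 3) and FLO8 fell (adjusted p = 0.00326). KSS1 and TEC1 are known to act in the pheromone response as well. G1/S (2 higher and 14 lower of 32; adjusted p = 0.133), M/G1 (4 and 5 of 20; adjusted p = 0.939), respiration (17 and 4 of 38; adjusted p = 0.169), the iron regulon (1 and 3 of 17; adjusted p = 0.636) and meiosis (8 and 1 of 17; adjusted p = 0.144) had no call as lists. Of 3 histone genes measured HHT1 and HTB1 fell, too few for a set test. The S. mikatae list calls held with an estimated correlation, except filamentous growth, for which none was computed. Apart from ribosome biogenesis, G1/S (15 lower) and respiration (18 higher), counts of the lists named here were unchanged when adjusted over the list alone.

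limma called 2095 of 4367 genes in S. mikatae, 1017 higher and 1078 lower, of which 138 changed at least 2-fold. As in S. paradoxus, probe mismatch was not measured, and 26.6% of probes gave no value on any S. mikatae array.

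**Figure D2:**
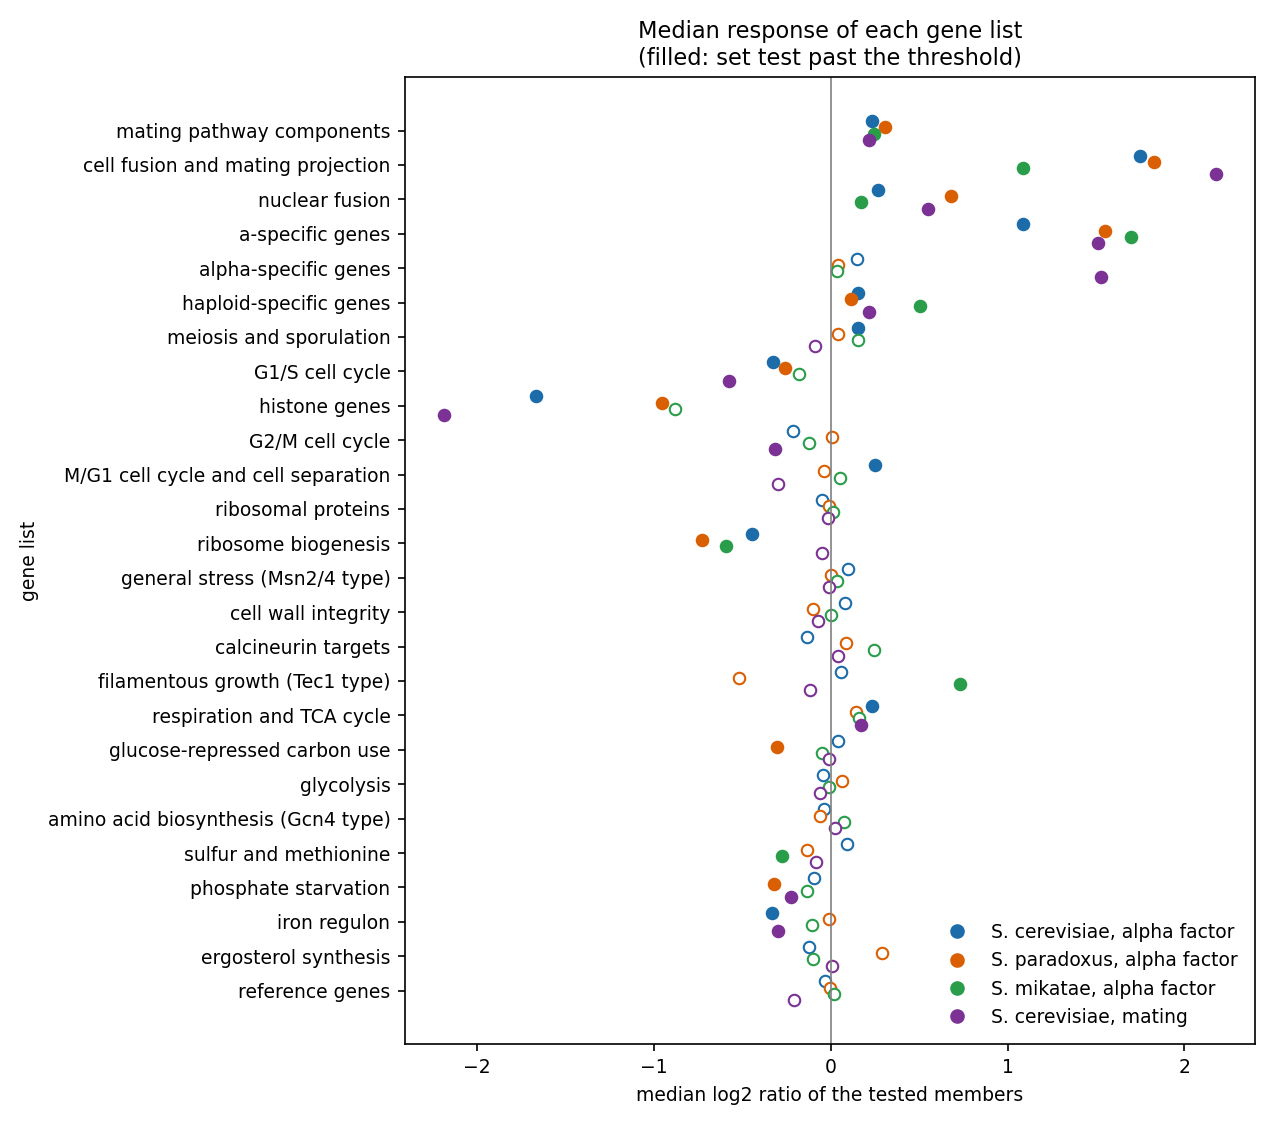
Median log2 ratio of the tested members (horizontal axis) of 26 gene lists (vertical axis) in the 4 groups, filled where the set test passed the threshold with the preset correlation and open where it did not or the list was too small. The ribosome biogenesis median is −0.73 in S. paradoxus and −0.59 in S. mikatae, and the cell fusion and a-specific medians lie above 0 in all 4 groups.

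When S. cerevisiae cells of both mating types were mixed, genes of both mating types rose. FIG1 rose by 4.97 ± 0.219 (n = 3; 31.4-fold; adjusted p = 9.72e-13), PRM3 by 3.88 ± 0.142, KAR4 by 3.25 ± 0.182, AGA2 by 3.14 ± 0.146, YDR124W by 2.77 ± 0.598 and ASG7 by 2.75 ± 0.0839. SAG1, the alpha-agglutinin of alpha cells, rose by 2.54 ± 0.11, MFA1 by 2.51 ± 0.449, AFR1 by 2.40 ± 0.172, FUS3 by 2.33 ± 0.0496 and STE3, the a-factor receptor of alpha cells, by 1.63 ± 0.161. MF(ALPHA)1 was at 0.55 ± 0.547 (adjusted p = 0.0625). The lowest were histone genes, HTB2 at −2.52 ± 0.141, HTA2 at −2.51 ± 0.247, HHF2 at −2.46 ± 0.299 and HHT2 at −1.92 ± 0.0652. SWA2, a clathrin uncoating factor, was at −2.04 ± 0.0639, the cell wall gene PIR1 at −1.83 ± 0.263, YBL113C at −1.74 ± 0.106, ANS1 at −1.68 ± 0.388, YOR248W at −1.67 ± 0.122 and the replication factor PSF2 at −1.58 ± 0.0908. CLB2 fell by 1.26 ± 0.237.

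Of 12 cell fusion genes measured on the mating arrays 9 rose, 10 when adjusted over the list alone, and none fell (adjusted p = 3.65e-48). Of 9 a-specific genes 7 rose and RAM1 fell (adjusted p = 1.19e-16), and of 5 alpha-specific genes 3 rose, 4 when adjusted over the list alone (SAG1, STE3 and MF(ALPHA)2 over all genes; adjusted p = 9.09e-10). Mating pathway components had 10 of 19 higher and PTP3 lower (adjusted p = 2.76e-10), nuclear fusion genes 4 of 8 higher and KAR2 and JEM1 lower (adjusted p = 3.45e-07), and haploid-specific genes 8 of 15 higher and 4 lower (adjusted p = 0.000197). Of 6 histone genes 5 fell and HTA1 rose by 0.22 (adjusted p = 3.65e-18). The G1/S list had 20 of 25 lower and PCL2 and SMC3 higher (adjusted p = 4.05e-07). The G2/M list had 10 of 16 lower, 12 when adjusted over the list alone, and SPO12 higher (adjusted p = 0.000134), with HOF1 of cytokinesis at −1.32 ± 0.0247. Of 12 iron regulon genes 7 fell (adjusted p = 0.0326). Of 27 respiration genes 11 rose and ATP3 fell (adjusted p = 0.0422, and adjusted p = 0.259 with an estimated correlation). Of 12 phosphate starvation genes 6 fell, 7 when adjusted over the list alone, and PHO86 rose (adjusted p = 0.0212, and adjusted p = 0.146 with an estimated correlation). Ribosome biogenesis genes had 3 higher and 5 lower of 46, with no call for the list (adjusted p = 0.552), nor had M/G1 (4 and 10 of 16; adjusted p = 0.119). The other mating list calls held with an estimated correlation, except histones, for which none was computed. Other counts were unchanged when adjusted over the list alone.

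limma called 1469 of 3712 genes in mating, 719 higher and 750 lower, of which 107 changed at least 2-fold. Without mating replicate 2 the count was 968. Both mating types contributed RNA to both channels, so a change in a cells cannot be told from a change in alpha cells, and 37.2% of probes, those of AGA1, PRM1 and FAR1 among them, gave no value.

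The responses of the 3 species were then compared with each other. S. cerevisiae was represented by BY4741 and S. paradoxus by a strain from CBS432. The arrays of a species replicate the strain used, so a difference between species cannot be told from a difference between strains. Of 4084 genes tested in all 3 species, 314 rose in each, where 36.56 would be shared if calls were independent, and 404 fell in each, where 46.28 would. Across genes, the Pearson correlation of the mean responses was 0.659 between S. cerevisiae and S. paradoxus (Spearman 0.584), 0.704 between S. cerevisiae and S. mikatae (Spearman 0.686) and 0.732 between S. paradoxus and S. mikatae (Spearman 0.707). It was 0.655 between alpha factor and mating in S. cerevisiae (Spearman 0.534), and 0.449 and 0.477 between mating and the other species' responses (Spearman 0.304 and 0.387). These 6 values are across genes, which are not independent replicates. Every array was read with the treated sample in channel 1. A dye effect of a probe would then recur in all groups and add to shared calls and correlations. It was not measured. Arrays of the same group correlated at 0.736 to 0.899.

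Between S. paradoxus and S. cerevisiae, 770 of 4718 genes differed, 428 higher and 342 lower in S. paradoxus, and 91 of them by at least 2-fold. MAK32 was higher by 3.68 (adjusted p = 3.72e-09), and ELO1, a fatty acid elongase, by 3.24, being at 2.30 ± 0.304 in S. paradoxus and −0.94 ± 0.131 in S. cerevisiae (adjusted p = 2.53e-07). The peroxidase GPX1 was higher by 1.97 and the chaperone gene BTN2 by 1.78. SCW11 was lower by −2.01, at −0.04 ± 0.124 against 1.97 ± 0.106 (adjusted p = 2.53e-07), PRM3 by −1.72 and PRM1 by −1.09 (adjusted p = 0.00462). STE2 was higher by 0.71 (adjusted p = 0.00464), FUS3 lower by −0.61 (adjusted p = 0.00389), and FIG1, KAR4, AGA1 and SST2 did not pass the test of a difference. M/G1 genes were lower in S. paradoxus (5 of 24, 10 when adjusted over the list alone; CDC6 higher; adjusted p = 8.17e-06), as were glucose-repressed genes (6 of 21, with 1 higher when adjusted over the list alone; adjusted p = 0.000716) and sulfur genes (4 of 20, 6 when adjusted over the list alone; adjusted p = 0.0177). The lower sulfur genes include MET17, deleted in BY4741, lower by −0.88. Any effect of that deletion on the sulfur list cannot be told from a species difference. Ribosome biogenesis genes were lower in 14 of 58, 17 when adjusted over the list alone (adjusted p = 4.14e-06, and adjusted p = 0.335 with an estimated correlation). G2/M genes were higher in 6 of 23, 7 when adjusted over the list alone (adjusted p = 0.0349), with the polo kinase CDC5 at 0.78 ± 0.414 against −0.60 in S. cerevisiae. Without S. cerevisiae replicate 1, S. cerevisiae replicate 3 or S. paradoxus replicate 1 the count of genes was 448, 446 and 475, and with array weights it was 1204. Probe mismatch can weaken ratios of S. paradoxus.

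Between S. mikatae and S. cerevisiae, 517 of 4357 genes differed, 278 higher and 239 lower in S. mikatae, and 61 of them by at least 2-fold. AGA1 was lower by −3.51 (adjusted p = 2.72e-06) and its fellow pheromone-responsive gene ECM18 by −1.999, at 0.28 ± 0.158 against 2.28 ± 0.18. FAR1 was lower by −1.19 (adjusted p = 0.00499), FUS3 by −0.86 and PRM1 by −1.17, while KAR4 was higher by 0.78 (adjusted p = 0.00425) and STE2 by 0.87 (adjusted p = 0.000866). Higher in S. mikatae by 2.14 to 2.39 were DCD1, YBL101WA, YHR125W, APT2, SKG6, KAE1 and the transporter PDR12. Of 20 sulfur and methionine genes 10 were lower, 11 when adjusted over the list alone (adjusted p = 2.03e-07), MET6 by −1.64 and MET14 by −1.57. MET17, deleted in BY4741, is counted among them, lower by −0.86. An effect of that deletion on the other genes of the list was not tested and cannot be told from a species difference. Of 20 M/G1 genes 7 were lower, 9 when adjusted over the list alone (adjusted p = 1.98e-07), SCW11 by −1.45 and the chitinase CTS1 by −0.68. Of 6 genes on the a-specific list 4 were higher, RAM1 among them, and STE14 lower (adjusted p = 0.000111), ASG7 by 1.21, and of 13 haploid-specific genes 5 were lower (STE4, STE18, FUS3, FAR1 and AMN1), with 1 higher when adjusted over the list alone (adjusted p = 0.00739). The count was 309 without S. cerevisiae replicate 1, 309 without S. cerevisiae replicate 3 and 856 with array weights. The S. cerevisiae arrays are shared by this and the preceding comparison, and probe mismatch can weaken ratios of S. mikatae.

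Between S. mikatae and S. paradoxus, 561 of 4090 genes differed, 247 higher and 314 lower in S. mikatae, and 56 of them by at least 2-fold. MAK32, outside the naming rule because it had no value on 1 of the 4 S. mikatae arrays, was lower by −4.002 (adjusted p = 1.12e-09). AGA1 was lower by −3.65 (adjusted p = 6.44e-07) and ELO1 by −3.00 (adjusted p = 1.45e-07). SKG6 was higher by 2.77, DCD1 by 2.54, PDR12 by 2.39 and the spliceosome factor PRP8 by 2.22. Phosphate starvation genes were higher in 3 of 12 (PHO84, VTC1 and VTC4), 6 when adjusted over the list alone (adjusted p = 0.000232), PHO84 by 2.02. Ergosterol genes were lower in 7 of 21, 9 with 1 higher when adjusted over the list alone (adjusted p = 0.000419, and adjusted p = 0.159 with an estimated correlation). Over all 3 species, 970 of 4084 genes differed in at least 1 pair by an F test in the same fit.

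**Figure D3:**
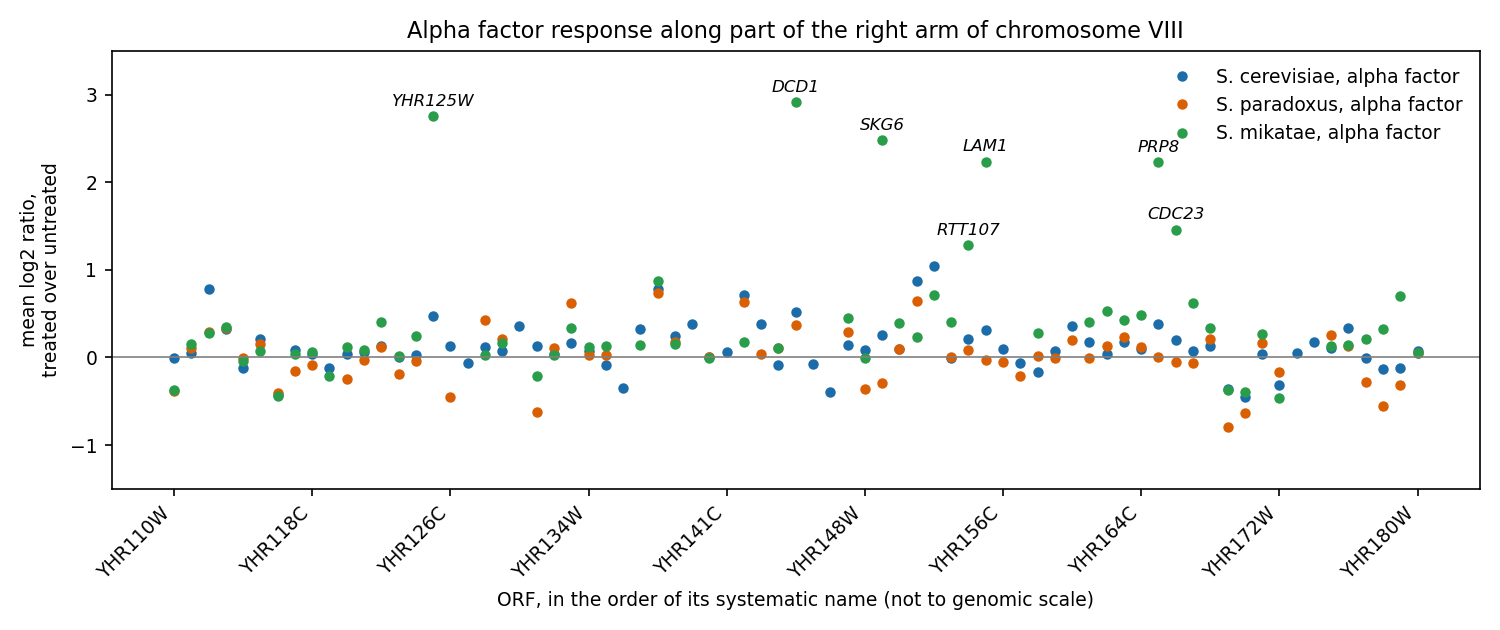
Mean log2 ratio after alpha factor (vertical axis) of each measured ORF, in the order of systematic names from YHR110W to YHR180W on chromosome VIII (horizontal axis, not to genomic scale), with colours for the 3 species. In S. mikatae the labelled probes YHR125W, DCD1, SKG6, RTT107, LAM1, PRP8 and CDC23 lie between 1.28 and 2.91.

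Between mating and alpha factor in S. cerevisiae, 584 of 3648 genes differed, 315 higher and 269 lower in mating, and 57 of them by at least 2-fold. The genes of alpha cells were among the highest, with SAG1 higher by 2.0 (2.54 ± 0.11 against 0.54 ± 0.276; adjusted p = 3.37e-06) and STE3 by 1.49 (adjusted p = 3.6e-06). MF(ALPHA)2 was higher by 1.13 and MATALPHA1, an alpha mating-type gene, by 1.08, while MFA1 was higher by 0.98 (adjusted p = 0.0118). PRM7 was at 0.24 ± 0.0694 in mating against −1.17 ± 0.222. NCE103, the carbonic anhydrase, was lower by −2.33 (adjusted p = 3.37e-06), PIR1 by −2.07, CLB2 by −0.82 (adjusted p = 0.000843) and KAR5 by −1.18. M/G1 genes were lower in 12 of 16 (adjusted p = 3.16e-13), with SCW11 lower by −1.32 and ASH1 by −1.31, and G2/M genes in 7 of 16 (adjusted p = 0.00108). Adjusted over the list alone these counts were unchanged, apart from 2 M/G1 genes then called higher. Of 46 ribosome biogenesis genes 20 were higher in mating and UTP4 lower, 30 and 1 when adjusted over the list alone (adjusted p = 2.6e-08, and adjusted p = 0.18 with an estimated correlation). NSR1 stood higher by 1.09 and DBP2 by 0.91. FIG1, KAR4, FUS1, FUS3, SST2 and HTB2 did not pass the test of a difference. Exposure time (60 and 90 min), support (liquid culture and filter) and mating types present differed together. So did the reference, cells taken before alpha factor or cells kept apart. None of these can be singled out. Without S. cerevisiae alpha factor replicate 1, alpha factor replicate 3 or mating replicate 2 the count of genes was 367, 294 and 366, and with array weights it was 914.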

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

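The tests of splits, of single arrays, of neighbouring probes, of placement, of mismatch and of the a-specific list without 2 members were chosen only after the results were seen. The prediction for a repeated RNA was written beforehand.

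Each difference between 2 groups' responses that passed its test is given here. Between S. paradoxus and S. cerevisiae 770 genes differed, and 584 between mating and alpha factor. The highest other split of the same arrays gave 1 and 0 genes, but 10 splits are too few, since the share is never under 0.1. Chance is unlikely for S. mikatae against S. cerevisiae (517 genes, highest other of 35 splits 45), for S. mikatae against S. paradoxus (561, highest other 67) and for any difference among species (970, highest other of 100 splits 217), where only 1 split, the real grouping, gave as many. No adjustment was made over these tests.

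In S. paradoxus, MAK32, YCL075W, YCL076W and YAL069W responded far more than in S. cerevisiae, by 3.68, 3.26, 3.26 and 3.29 log2. A rise on a single array is excluded by the lowest of their array values, 3.08. The naming rule had already required no overlap between the arrays. The 12 nearest other measured probes had a median of 0.29 with a range of −0.62 to 0.98, so a shift that reaches them is excluded. They lie on a single side of YCL075W, YCL076W and YAL069W. YCL075W and YCL076W, adjacent by name, were not counted as neighbours of each other, so a shift of that pair stays open. A single repeated RNA read by several probes may be the source and stays open, because the lowest correlation between 2 of the probes, 0.342, rests on 3 arrays. A biological difference between the species is untested.

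In S. mikatae, 7 of the 31 tested probes from YHR125W to CDC23 on the right arm of chromosome VIII were raised against S. cerevisiae, among 34 of 4357 over all genes. The highest number in any stretch of that length in 10000 random placements was 5 (permutation test of the placements, p = 1e-04, the smallest they can give). Every chromosome was searched in each placement, so the position of the stretch is accounted for. Its length, set to start and end at a raised probe, is not. At that length the counts argue against chance placement, and the choice of length was not tested. A shift of all 31 probes by as much as the raised ones, with a median of 1.92, is excluded. The median difference over all 31 was 0.21 (SD 0.842). Of the other 24 probes 14 were higher in S. mikatae, with a median difference of 0.09 (SD 0.303). The raised probes were picked by their difference, so a smaller shift, or a shift of part of the stretch, stays open. A rise on a single array is excluded by the lowest array value of the raised probes, 0.85. A strain or species difference in a few transcripts, or RNA of other genes that matches these probes, may explain them and was not tested.

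Genes that responded more outside S. cerevisiae made up 67.9% of the 517 differences in S. mikatae and 73.6% of the 770 in S. paradoxus. With arrays scaled to a common spread or quantile normalized these shares were 53% to 56.9%, so most of the excess goes with the scaling. Compressed ratios keep their sign, so they do not by themselves give opposite calls, but false calls in either response can. Genes called in opposite directions in S. paradoxus and S. cerevisiae were 6.97% of 1062, above a bound of 5% set for false calls. In S. mikatae the share, 4.45% of 1033, lay under that bound. The bound is that of a single response and these genes were picked by their signs, so neither share decides. Compressed ratios stay open in both species. Mismatch stays open for 5 genes with little response in S. mikatae, among them AGA1 at 0.17, ECM18 at 0.28, PRM7 at −0.36 and PHO84 at −0.05.

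Other genes differing between S. paradoxus and S. cerevisiae were ELO1 (3.24), GPX1 (1.97), BTN2 (1.78), HEL2 (1.75), GLN1 (−2.06), SCW11 (−2.01), CSS1 (−2.001), YLL053C (−1.99), NFG1 (−1.91), PCK1 (−1.76), MET6 (−1.73) and PRM3 (−1.72). Between S. mikatae and S. cerevisiae they were DCD1 (2.39), YBL101WA (2.36), YHR125W (2.29), APT2 (2.28), SKG6 (2.22), KAE1 (2.19), PDR12 (2.14), YAR009C (2.01), AGA1 (−3.51), CSS1 (−2.25), YIL082W-A (−2.07), ECM18 (−1.999), MET6 (−1.64), MET14 (−1.57), YLL053C (−1.55) and YOR342C (−1.45). Between S. mikatae and S. paradoxus they were SKG6 (2.77), DCD1 (2.54), PDR12 (2.39), LAM1 (2.27), YAR009C (2.25), PRP8 (2.22), APT2 (2.13), IRC7 (2.05), AGA1 (−3.65), ELO1 (−3.00), ECM18 (−2.21), MCM21 (−1.63), LYS9 (−1.34), UTR2 (−1.28), MEX67 (−1.24) and MVD1 (−1.24). MAK32, outside the naming rule with a value on 3 of 4 S. mikatae arrays, was lower still (−4.002). Between mating and alpha factor they were SAG1 (2.0), STE3 (1.49), XBP1 (1.42), LIF1 (1.41), PRM7 (1.41), HEM13 (1.36), TSL1 (1.36), HSP30 (1.36), NCE103 (−2.33), PIR1 (−2.07), ANS1 (−1.82), YNL058C (−1.41), TSA2 (−1.39), SLM1 (−1.36), SRL1 (−1.34) and YOR248W (−1.34).

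Gene lists that were higher in S. paradoxus than in S. cerevisiae were ergosterol synthesis (9 of 22, 11 when adjusted over the list alone; adjusted p = 0.00329, and adjusted p = 0.269 with an estimated correlation), G1/S (7 of 35; adjusted p = 0.00919, and adjusted p = 0.212 with an estimated correlation), G2/M (6 of 23; adjusted p = 0.0349) and the iron regulon (6 of 22; adjusted p = 0.036, and adjusted p = 0.0508 with an estimated correlation). The a-specific list was higher too (4 of 10; adjusted p = 0.0105, and adjusted p = 0.167 with an estimated correlation), but its median of 0.43 became −0.10 when arrays were scaled to a common spread, and without RAM1 and STE14 its unadjusted camera p was 0.105 (3 of 8 higher, 1 lower). Lower lists were ribosome biogenesis (14 of 58; adjusted p = 4.14e-06, and adjusted p = 0.335 with an estimated correlation), M/G1 (5 of 24; adjusted p = 8.17e-06), glucose-repressed carbon use (6 of 21; adjusted p = 0.000716), sulfur and methionine (4 of 20; adjusted p = 0.0177) and phosphate starvation (3 of 14; adjusted p = 0.0202, and adjusted p = 0.0762 with an estimated correlation).

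Higher lists in S. mikatae than in S. cerevisiae were the a-specific list (4 of 6, RAM1 among them; adjusted p = 0.000111, and without RAM1 and STE14 3 of 4, too few for a set test), G1/S (6 of 32; adjusted p = 0.000773, and adjusted p = 0.0833 with an estimated correlation) and the iron regulon (FET4, ISU2, HMX1 and FRE1; 4 of 17; adjusted p = 0.0454, and adjusted p = 0.0627 with an estimated correlation). Lower ones were M/G1 (7 of 20; adjusted p = 1.98e-07), sulfur and methionine (10 of 20; adjusted p = 2.03e-07), ribosome biogenesis (7 of 62; adjusted p = 0.0011, and adjusted p = 0.546 with an estimated correlation) and the haploid-specific genes (5 of 13; adjusted p = 0.00739). Against S. paradoxus, S. mikatae had phosphate starvation genes higher (3 of 12; adjusted p = 0.000232) and ergosterol genes lower (7 of 21; adjusted p = 0.000419, and adjusted p = 0.159 with an estimated correlation). In mating against alpha factor, ribosome biogenesis was higher (20 of 46; adjusted p = 2.6e-08, and adjusted p = 0.18 with an estimated correlation), and M/G1 (12 of 16; adjusted p = 3.16e-13), G2/M (7 of 16; adjusted p = 0.00108), nuclear fusion (KAR5 and CIK1, 2 of 8; adjusted p = 0.04) and general stress (6 of 29; adjusted p = 0.0349, and adjusted p = 0.0627 with an estimated correlation) were lower.

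ACT1 had an array at 0.23 in S. mikatae, far from the other 3. It was 1 of 30 genes tested for such an array, where chance gives about 1 in 20, or 1.5.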

How the results depend on the processing

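The check of list medians under scaling was chosen after the results were seen, and the other tests in this part before. No result changed its tested direction under the alternatives. The median of the a-specific list in S. paradoxus minus S. cerevisiae did, from 0.43 to −0.10 with arrays scaled to a common spread. Without centring, the 818 single genes and gene lists compared kept their side of the threshold, and over all genes 1940 of 1946 S. cerevisiae calls and 760 of 770 for S. paradoxus minus S. cerevisiae were shared. The median over spots was not run, since each ORF has 1 value. Signal over background is not used here, so how far weak spots limit the calls was not measured.

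With only the 2194 genes measured on all 13 arrays, fewer genes are tested by construction. The counts were 823 (S. cerevisiae), 1193 (S. paradoxus), 1245 (S. mikatae), 936 (mating), 421 (S. paradoxus minus S. cerevisiae) and 341 (S. mikatae minus S. cerevisiae). Correlations across genes were then 0.742 (S. cerevisiae and S. paradoxus), 0.778 (S. paradoxus and S. mikatae) and 0.613 (alpha factor and mating). Array weights gave 1204 for S. paradoxus minus S. cerevisiae, 856 for S. mikatae minus S. cerevisiae and 914 for mating minus alpha factor, and the cause was not tested. With a replicate block fewer genes could be tested, and the counts were 1230 of 4233 for S. cerevisiae (5789 tested without it), 946 of 2730 for mating (3712) and 337 of 4233 for S. mikatae minus S. cerevisiae (4357). How much of each drop the fewer genes explain was not tested. A log2 change of at least 1, which removes small changes by construction, left 140, 194, 138 and 107 genes in the responses (S. cerevisiae, S. paradoxus, S. mikatae and mating). It left 91, 61, 56 and 57 in the differences. Of the tests of gene lists, 66 passed the threshold with camera, 104 with directional fry and 162 with mixed fry, which test another hypothesis.

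Leaving out each array in turn leaves fewer arrays by construction. It gave 1124 to 1402 genes in S. cerevisiae, 968 to 1099 in mating, 446 to 703 for S. paradoxus minus S. cerevisiae, 309 to 492 for S. mikatae minus S. cerevisiae and 294 to 498 for mating minus alpha factor. The arrays that moved a count most were S. cerevisiae replicate 1 (448, 309 and 367 in these differences), S. cerevisiae replicate 3 (446, 309 and 294, and 1124 in S. cerevisiae), S. paradoxus replicate 1 (475) and mating replicate 2 (968, and 366 for mating minus alpha factor). S. paradoxus ranged over 1666 to 1869, S. mikatae over 1762 to 1861, S. mikatae minus S. paradoxus over 379 to 528 and any species over 698 to 965.

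Of the single genes and gene lists compared with arrays scaled to a common spread, 37 of 752 lost their call and 1 gained it. With quantile normalization 24 lost it and 1 gained it, with only the arrays compared 34 and 2, with robust eBayes 3 and 0, and with array weights 4 and 13. With an estimated correlation 17 of 64 list calls were lost.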

Other observations

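The purine list, the neighbour values and the proteasome and chaperone tests were chosen only after related values were seen. The proteasome and chaperone predictions were written before their tests.

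A list of purine and one-carbon genes, made after their values were seen and not tested as a set, had medians that differed between arrays of a group. The median per array was −0.48, −0.32 and −1.02 in S. cerevisiae, −0.76, −0.17 and −1.56 in S. paradoxus, −1.23, −0.26, −0.44 and −1.20 in S. mikatae, and 0.09, −0.11 and −0.00 in mating. ADE6 did not pass in any species, at 0.01, 0.10 and 0.07. ADE17 stood at −1.22, −1.05 and −2.97 on the S. cerevisiae arrays and at −3.01, −1.19, −1.21 and −3.16 on those of S. mikatae.

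Some retrotransposon ORFs, picked after their values were seen, had large ratios. In S. mikatae YAR009C was at 2.04, YBL101WA at 2.29 and YBL005W-A at 1.30, against 0.03, −0.07 and 0.01 in S. cerevisiae, and YIL082W-A was at −0.02 against 2.05. In S. cerevisiae YIL082W was at 3.05 and YIL080W at 2.07, with no value in the other species. Some others there lay near 0 or lower, such as YAR010C at 0.06, YCL019W at −0.05 and YMR045C at −0.78. Not all did: YCL074W was at 1.36 in S. cerevisiae, and YCL075W and YCL076W, adjacent to it by name, were at 0.645 and 0.87. These ORFs were not tested as a group.

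Proteasome genes were compared between species, both differences sharing the same 3 S. cerevisiae arrays. Without PRE3, PRE4, RPN6 and RPN10, which had been seen first, 8 of 26 were higher in S. paradoxus (median 0.34) and 13 of 28 in S. mikatae (median 0.35), none lower. The higher of the 2 adjusted p-values with an estimated correlation was 0.0101. With arrays scaled to a common spread or quantile normalized, alternatives added after the data were seen, it was 0.151 and 0.0856 for S. paradoxus, past the threshold no longer, and 0.0474 and 0.0223 for S. mikatae. In the responses 13 of 28 rose in S. cerevisiae, 21 of 26 in S. paradoxus and 22 of 28 in S. mikatae, with 1 lower in each of the latter, RPN13 at −0.58 and −0.47, and PRE1 at 0.27, 0.84 and 0.74. Whether proteasome genes respond more outside S. cerevisiae stays open.

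Chaperone genes were tested in the same way, without HSC82, SIS1, HSP104, CDC37 and BTN2. In S. paradoxus 4 of 16 were higher and 1 lower than in S. cerevisiae (median 0.14), and the test did not pass (adjusted p = 0.186, and 0.15 with an estimated correlation). In S. mikatae 1 of 16 was higher (adjusted p = 0.323).

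MET17, deleted in BY4741, read 0.47 in S. cerevisiae, −0.41 in S. paradoxus and −0.39 in S. mikatae. It is counted among the called sulfur and methionine genes in S. cerevisiae and in both species' differences from S. cerevisiae. The source of the S. cerevisiae value was not tested, nor was an effect of the deletion on the other genes of that list.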
